A study of Bos taurus with 47 samples.

How the data were processed

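The series held 47 bovine mRNA sequencing libraries in 12 groups. Fibroblasts and mature (MII) oocytes were profiled beside embryos made by in vitro fertilization (IVF) or by somatic cell nuclear transfer (scNT), in which the nucleus of a somatic cell is placed in an enucleated oocyte. Embryos were taken at the 2-cell, 8-cell, morula and blastocyst stages, and cells derived from blastocysts were also profiled. Every group had 4 libraries except scNT morulae, with 3, numbered 2, 3 and 4 in the labels. Groups and replicate numbers were taken from the sample titles. Per the labels, embryos were collected as pools of 20 on days 2, 3, 6 and 8 after IVF or scNT. Nothing in the labels ties a replicate to a separate animal or culture, so p-values measure only the spread between these pools, which may be technical. The labels' texts differ on the number of pools per stage, and the numbers of libraries given here are those in the table.

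Per the labels' protocols, RNA longer than 200 nt was made into libraries with a low-input kit that uses several rounds of PCR. Use of molecular identifiers is not given in the sources used here, so reads are not taken as independent molecules and statements about depth cover counting error only. Per the submitters' processing notes, FastQC, MultiQC, STAR and DESeq2 were used with genome build UMD3.1. Their versions, roles, the annotation and the read counter are not given in the sources used here. The deposited signal was 1 normalized count per gene and library, written with 1 decimal, for 20526 genes. Within each library the values were whole multiples of a single step, between 0.477 and 2.04. With a tolerance of 0.05, between 99.9% and 100% of the values above 0 were whole reads, against at most 21.0% by chance. The recovered totals ran from 4608099 to 16642362 reads. Among the 69 pairs of replicate libraries the lowest chi-square per degree of freedom was 6.67, so no pair differed by as little as sampling noise.

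The genes are given by Ensembl identifiers, and the files do not pair them with gene names. Of the 20526 identifiers, 0 matched the reference table used here (assembly ARS-UCD2.0). None of the 21 lists of named genes fixed beforehand could therefore be used, which gave 0 matched lists, and their tests, including those for markers of other cell types, were not run. At most 2 identifiers per direction are printed for a comparison. The rule fixed for naming genes took those with an adjusted p under 0.05, a mean of at least 50 and no overlap between the groups' libraries, ordered by the size of the change. For differences between steps the rule ordered genes with a mean of at least 50 by adjusted p. The 4 genes called between scNT and IVF 2-cell embryos were exempt from the conditions on mean, overlap and order. The rule asked for a gene symbol, a condition that could not be applied.

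Genes with a value of at least 10 in at least as many libraries as the smaller group were tested with limma 3.58.1 (trend and robust options) in R 4.3.3. The test used log2(value + 1), took only the groups compared and had no replicate block. Fold changes are on that scale, which understates changes of low genes. All tests were two-sided and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were scNT against IVF at 5 stages, each developmental step within a method, fibroblasts against oocytes, and the difference between the scNT and IVF steps as an interaction term. Unless the text says otherwise, these comparisons, their tests and the alternatives were chosen before the data were examined.

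Gene sets were made from the libraries because no named list could be used. Fibroblast-high and oocyte-high genes differed at least 32-fold between fibroblasts and oocytes with an adjusted p under 0.05. They were tested in scNT against IVF with limma's camera at a preset correlation of 0.01, adjusted over both sets and the 5 stages. Rising and falling genes, chosen after the principal components were seen, changed at least 4-fold between the IVF or oocyte groups on either side of a stage, so that the stage itself took no part in the choice. Each set was also tested with an estimated correlation between genes, with fry, which asks whether a set's genes move on balance one way, and by an exact permutation of library means. The smallest p that such a permutation can give is 0.0286, both for 4 libraries against 4 and for 3 against 4.

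The fit was tested on simulated data in which 200 genes with a mean of at least 50 were changed by known amounts. At a log2 change of 1 it recovered 28.8% of the changed genes in the 2-cell comparison (12195 genes), 16.7% at the 8-cell stage (13000), 36.4% in morulae (13590), 74.2% in blastocysts (12607) and 69.7% in blastocyst-derived cells (12390). At a log2 change of 2 the recovery was 88.1%, 88.1%, 95.5%, 95.5% and 94.0%. Between 3.4% and 9.2% of the genes called in these simulations had not been changed. In a simulated set test a raised set gave a camera p of 5.76e-153 and a set left unchanged gave 0.654. Genes were drawn independently in these simulations, so they cannot show how camera behaves where genes of a set move together. In the real sets the estimated correlation lay between 0.024 (oocyte-high, blastocyst-derived cells) and 0.762 (fibroblast-high, 2-cell stage).

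Same-numbered libraries were checked for pairing by correlating their deviations from the group means. By the rule used, which rests on the lowest same-number correlation, only the scNT and IVF 8-cell libraries paired. Their correlations lay between 0.224 and 0.512, and 8 of 8 libraries were closest to the library of their own number. The mean was 0.390, against -0.131 for other numbers. At the 2-cell stage the means were alike, 0.393 and -0.112, but the lowest pair had 0.049. A shared factor at the 2-cell stage is therefore not excluded. The 8-cell pairing rests on the data, since the labels do not say what a shared number marks. Alternatives were pseudocounts of 10 and 0.5, no filter on low values, equal library totals, median-of-ratios scaling within a comparison, all groups in a single fit, library weights, a 2-fold threshold, the replicate block, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for recovery of reads, principal components and figures. Small RNA profiles named in the series title were not analysed here.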

Results

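Transcript levels were compared between bovine embryos made by IVF and by scNT from the 2-cell embryo to cells derived from blastocysts, with oocytes and fibroblasts as the starting cells. The 47 libraries held between 4608099 and 16642362 recovered reads. Oocyte libraries held 8709911 to 14281462 reads and fibroblast libraries 10082317 to 14669082. IVF libraries held 5939973 to 16642362 at the 2-cell stage, 6413054 to 11306619 at the 8-cell stage, 4783919 to 8241675 in morulae, 4608099 to 7062383 in blastocysts and 7858754 to 9342097 in blastocyst-derived cells. The scNT libraries held 6680061 to 12374138, 9028054 to 15274177, 5663196 to 8168033, 6340918 to 8402703 and 7590056 to 10318674 reads at the same stages. Libraries of a group correlated with each other at a mean r between 0.846 and 0.985 on the log2 scale. The lowest values belonged to fibroblast replicate 3, at 0.846, and IVF 2-cell replicate 3, at 0.858.

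The first 3 principal components of 14001 genes held 54.6%, 18.1% and 9.85% of the variance. Along the first component oocytes, 2-cell and 8-cell embryos of both methods lay on one side, followed by morulae, blastocysts and blastocyst-derived cells in the order of their stages. The scNT morulae lay between the IVF morulae and the blastocysts of both methods.

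**Figure D1:**
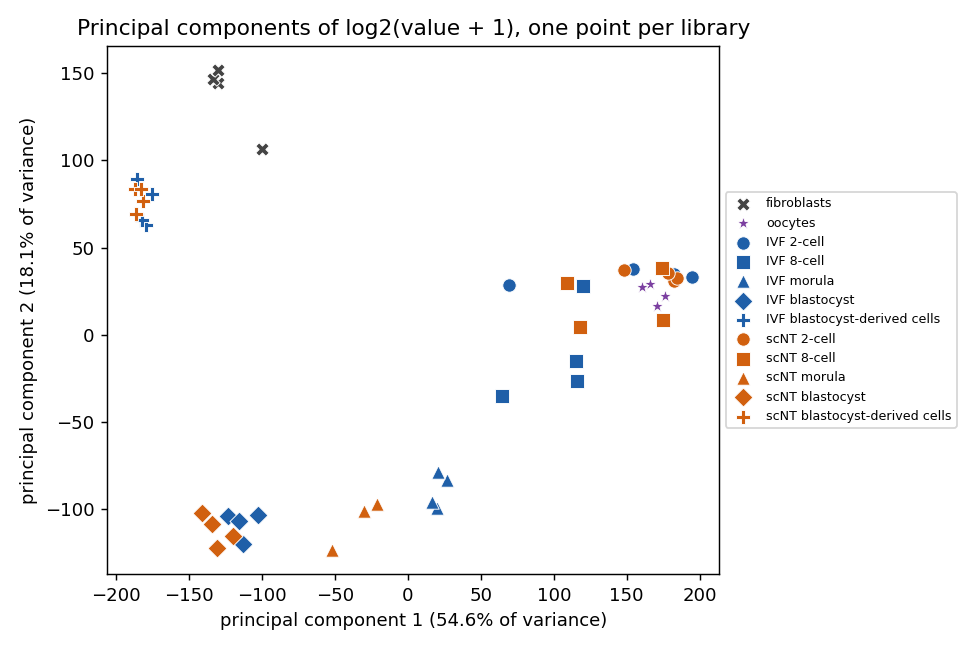
Scores of each library on the first and second principal components (54.6% and 18.1% of the variance) of log2(normalized count + 1), with 1 point per library, coloured by method and shaped by stage. Fibroblast replicate 3 and IVF 2-cell replicate 3 lie apart from their groups.

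Fibroblasts, the somatic cells profiled, and oocytes differed in most genes. Of 13191 genes tested, 10335 (78.3%) differed, 4902 higher in fibroblasts with a median log2 difference of 2.35 and 5433 higher in oocytes with a median of -2.37 (limma, Benjamini-Hochberg, n = 4 and 4). The gene ENSBTAG00000021466 had a mean of 58350 ± 39100 normalized counts in fibroblasts and 3.08 ± 2.73 in oocytes (SD, n = 4 each). The gene ENSBTAG00000034346 had 1.45 ± 0.50 in fibroblasts and 22540 ± 3920 in oocytes. A difference of at least 32-fold was met by 546 genes higher in fibroblasts and 938 genes higher in oocytes. With equal library totals the median of all genes moved from -0.14 to -0.53. Fibroblast replicate 3 differed from the other fibroblast libraries in both sets. Its fibroblast-high genes had a mean log2 value of 7.93 and its oocyte-high genes 2.39, while the nearest of the others had 9.57 and 1.37.

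Oocyte-high genes had lower means at each later stage of both kinds of embryo, and fibroblast-high genes had higher means in blastocyst-derived cells than in embryos. Oocyte-high genes had a mean log2 value of 8.52 ± 0.024 in oocytes (SD, n = 4). In IVF embryos they had 8.18 ± 0.54, 7.84 ± 0.37, 6.99 ± 0.064 and 4.50 ± 0.20 from the 2-cell stage to the blastocyst and 3.13 ± 0.12 in blastocyst-derived cells (n = 4 each). In scNT embryos they had 8.45 ± 0.12, 8.27 ± 0.30, 5.76 ± 0.54 and 4.08 ± 0.26 at those stages and 3.02 ± 0.078 in blastocyst-derived cells (n = 3 for morulae, 4 otherwise). Fibroblast-high genes had 2.73 ± 0.37 in oocytes and 9.21 ± 0.85 in fibroblasts. Their means were 3.68 ± 1.80, 4.89 ± 0.48, 4.96 ± 0.30, 5.45 ± 0.084 and 6.83 ± 0.30 along the IVF stages and 3.42 ± 0.75, 4.43 ± 1.00, 5.24 ± 0.19, 5.26 ± 0.12 and 6.78 ± 0.18 along the scNT stages.

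**Figure D2:**
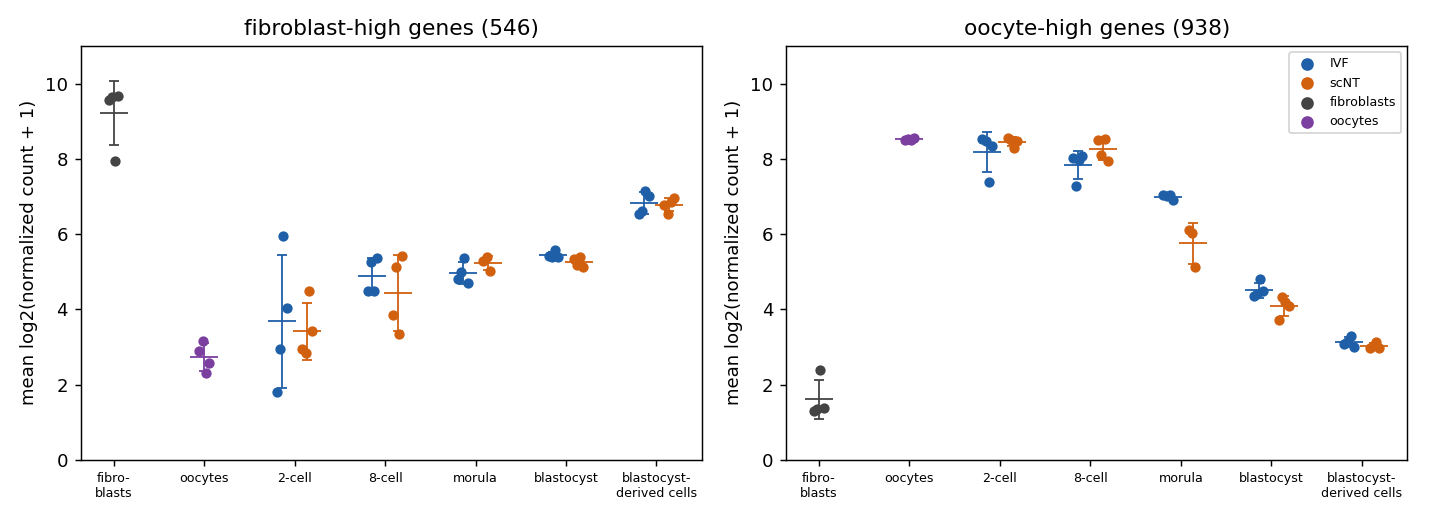
Mean log2(normalized count + 1) of the fibroblast-high genes and of the oocyte-high genes in fibroblasts, oocytes and each stage of IVF and scNT embryos, with 1 point per library and bars for the group mean ± SD. Oocyte-high genes stood at 6.99 in IVF morulae and 5.76 in scNT morulae.

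Few genes were called in the early steps of IVF development. Between oocytes and IVF 2-cell embryos 130 of 12313 genes changed, 3 higher and 127 lower, with a median log2 change of -1.32 among the latter. The gene ENSBTAG00000007392 had 1465 ± 532 normalized counts in oocytes and 56.1 ± 7.87 in IVF 2-cell embryos (SD, n = 4 each; limma, Benjamini-Hochberg adjusted p = 2.75e-05). Without IVF 2-cell replicate 3 the number rose to 646. It was 28, 32, 23 and 27 without oocyte replicates 1 to 4, and 33 and 37 without IVF 2-cell replicates 2 and 4. Between IVF 2-cell and 8-cell embryos 34 of 12904 genes changed, 30 higher with a median of 4.82 and 4 lower with a median of -1.94 (limma, Benjamini-Hochberg). This number rested on single libraries. It was 1491 without IVF 2-cell replicate 3, 662 without IVF 8-cell replicate 4, 3 without IVF 8-cell replicate 1, and 0 without any other single library. The count at an unadjusted p under 0.05 was 1991, DESeq2 called 667 genes and edgeR 0.

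From the 8-cell embryo to the morula 6148 of 13407 genes changed in IVF embryos, 2656 higher with a median log2 change of 1.46 and 3492 lower with a median of -1.03. From the morula to the blastocyst 7996 of 13354 changed, 3950 higher and 4046 lower, with medians of 0.98 and -1.32. Between blastocysts and blastocyst-derived cells 8762 of 13099 differed, 4268 higher and 4494 lower in the derived cells, with medians of 1.40 and -1.16 (limma, Benjamini-Hochberg, n = 4 and 4 throughout). The gene ENSBTAG00000017020 had 1.58 ± 1.89 normalized counts in IVF blastocysts and 16960 ± 5490 in the derived cells, and ENSBTAG00000039346 had 7359 ± 1750 and 4.08 ± 3.90 (SD, n = 4 each). With equal library totals the split from morula to blastocyst became 2136 higher and 5968 lower, as the median of all genes moved from 0.03 to -0.38.

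The scNT embryos changed along the same steps. Between oocytes and scNT 2-cell embryos 2256 of 12210 genes differed, 1200 higher with a median log2 difference of 0.47 and 1056 lower with a median of -0.84 (limma, Benjamini-Hochberg, n = 4 and 4). Only 49 of the higher genes and 380 of the lower ones differed at least 2-fold. The gene ENSBTAG00000021466, also higher in fibroblasts than in oocytes, had 180.0 ± 47.6 normalized counts in scNT 2-cell embryos and 3.08 ± 2.73 in oocytes (SD, n = 4 each; limma adjusted p = 0.000157). With equal library totals the split became 334 higher and 1598 lower, as the median of all genes moved from 0.06 to -0.10, and with median-of-ratios scaling it was 688 and 1129. The number was 789 without scNT 2-cell replicate 4, 1235 without replicate 2, and 1305 and 1215 without oocyte replicates 1 and 4. Between scNT 2-cell and 8-cell embryos 706 of 12425 genes changed, 102 higher with a median of 1.52 and 604 lower with a median of -0.86. It was 225 higher and 583 lower with equal library totals. The number was 312, 266 and 320 without scNT 2-cell replicates 1, 2 and 4, 442 without scNT 8-cell replicate 2 and 1059 without scNT 8-cell replicate 1.

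From the scNT 8-cell embryo to the morula 9438 of 13702 genes changed, 4278 higher with a median log2 change of 1.96 and 5160 lower with a median of -1.91 (limma, Benjamini-Hochberg, n = 4 and 3). From the morula to the blastocyst 6315 of 13236 changed, 2855 higher and 3460 lower, with medians of 1.19 and -1.21. Between scNT blastocysts and their derived cells 8571 of 12786 differed, 4207 higher and 4364 lower, with medians of 1.49 and -1.13 (n = 4 and 4). The gene ENSBTAG00000016748 had 8966 ± 1640 normalized counts in scNT blastocysts and 0.225 ± 0.45 in the derived cells (SD, n = 4 each). With equal library totals the splits became 1518 higher and 5777 lower from morula to blastocyst and 5347 higher and 3156 lower for the derived cells, as the medians of all genes moved from -0.09 to -0.49 and from -0.03 to 0.26.

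The steps of the 2 methods, which share no library, called many genes in common. From the 8-cell embryo to the morula 2370 genes rose in both methods and 3063 fell in both, where independent lists of those sizes would share 810 and 1313. Only 1 gene moved in opposite directions. From the morula to the blastocyst 2377 rose and 2543 fell in both (844 and 981 for independent lists) and 26 moved in opposite directions. For blastocyst-derived cells against blastocysts 3534 were higher and 3644 lower in both (1368 and 1441) and 23 were opposite. From the 2-cell to the 8-cell embryo 6 rose and 4 fell in both (0.0914 and 0.197).

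At the 2-cell stage scNT and IVF embryos differed in 4 of 12195 genes, all higher in scNT embryos, and 405 genes had an unadjusted p under 0.05. The gene ENSBTAG00000005250 had 57.8 ± 20.4 normalized counts in scNT and 1.30 ± 2.22 in IVF embryos, and ENSBTAG00000030190 had 63.6 ± 40.8 and 1.18 ± 0.544 (SD, n = 4 each; limma, Benjamini-Hochberg adjusted p = 0.0184 and 0.00762). All 4 belonged to the fibroblast-high genes. Of the 263 fibroblast-high genes tested the median log2 difference was nevertheless -0.55, with a camera adjusted p = 2.46e-04, and adjusted p = 0.701 with an estimated correlation. The 936 oocyte-high genes had a median of 0.25, with a camera adjusted p = 5.57e-10, and adjusted p = 0.602 with an estimated correlation. Both medians rested on IVF 2-cell replicate 3, in which fibroblast-high genes had a mean log2 value of 5.95 and oocyte-high genes 7.38, against at most 4.03 and at least 8.33 in the other IVF 2-cell libraries. Without it the medians were 0.32 and -0.007, so that camera called the fibroblast-high genes higher in scNT embryos (adjusted p = 4.81e-08) and no longer called the oocyte-high genes (adjusted p = 0.352). Without IVF replicate 4 the fibroblast-high median was -0.297 and its call was lost (camera adjusted p = 0.0524). With equal library totals it was -0.68 and the call was also lost (camera adjusted p = 0.437). It was -1.41 and -0.86 without IVF replicates 1 and 2 and -0.356, -0.347 and -0.961 without scNT replicates 1 to 3, and the oocyte-high median was 0.383 without IVF replicate 1 and 0.117 with equal library totals. The 515 genes that rose at least 4-fold between the oocyte and the IVF 8-cell embryo had a median of -0.55 (camera adjusted p = 8.04e-16, and adjusted p = 0.428 with an estimated correlation), which was 0.09 without IVF replicate 3 (camera adjusted p = 0.351), -1.15 and -0.872 without IVF replicates 1 and 2 and -0.819 without scNT replicate 3. The 143 that fell had 0.33 (camera adjusted p = 9.08e-07, and adjusted p = 0.428 with an estimated correlation), which was 0.13 without IVF replicate 3 and 0.189 with equal library totals. By fry these 4 sets had adjusted p = 0.911, 0.544, 0.626 and 0.360. The number of genes called was 8 without IVF replicate 3, 1 without IVF replicate 1 or 4, 2 without scNT replicate 3, and 0 without IVF replicate 2 or scNT replicate 1, 2 or 4. DESeq2 called 9 genes and edgeR 2.

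Genes abundant in fibroblasts and low in oocytes and early IVF embryos were then followed, a choice made after the values of the 4 genes had been seen. For the 2-cell stage they were the 24 genes with a fibroblast mean of at least 1000 normalized counts and at most 20 in every oocyte and IVF 8-cell library. Their mean log2 value was 3.65 ± 0.18 in scNT and 1.36 ± 0.43 in IVF 2-cell embryos, a difference of 2.30 (SD, n = 4 each; exact permutation p = 0.0286, the smallest the design allows), and 23 of the 24 were higher in scNT embryos. All 4 called genes were in the list, and without them the other 20 had 3.25 ± 0.17 and 1.41 ± 0.42, a difference of 1.84 (exact permutation p = 0.0286). For the 8-cell stage the 24 genes were chosen with IVF 2-cell in place of IVF 8-cell libraries, and 23 genes were in both lists. Their mean log2 value was 3.55 ± 0.27 in scNT and 1.80 ± 0.23 in IVF 8-cell embryos, a difference of 1.75 (n = 4 each; exact permutation p = 0.0286), or 1.38 without the 4 called genes. It was positive in 4 of 4 same-numbered pairs (exact sign flips p = 0.125, the smallest possible). The choice asks for low values in IVF and not in scNT embryos, so it was repeated with scNT in place of IVF libraries. The difference was then 1.49 for 14 genes at the 2-cell stage (exact permutation p = 0.0286) and 1.05 for 19 genes at the 8-cell stage (exact permutation p = 0.0571; positive in 4 of 4 pairs, exact sign flips p = 0.125). For the 62 genes chosen by oocytes alone it was 1.06 and 0.60 (exact permutation p = 0.314 and 0.257; positive in 4 of 4 pairs at the 8-cell stage, exact sign flips p = 0.125), and 30 and 41 of them were higher in scNT embryos. The median level was 0.345% of that in fibroblasts in scNT 2-cell embryos and 0.365% in scNT 8-cell embryos, against 0.0359% and 0.0818% in IVF embryos. The genes of the 2-cell list stood at 1.09 ± 0.11 in oocytes. They stood at 2.96 ± 0.31 and 2.45 ± 0.18 in scNT and IVF morulae, at 2.96 ± 0.19 and 2.75 ± 0.23 in blastocysts and at 5.45 ± 0.42 and 5.49 ± 0.41 in blastocyst-derived cells.

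**Figure D3:**
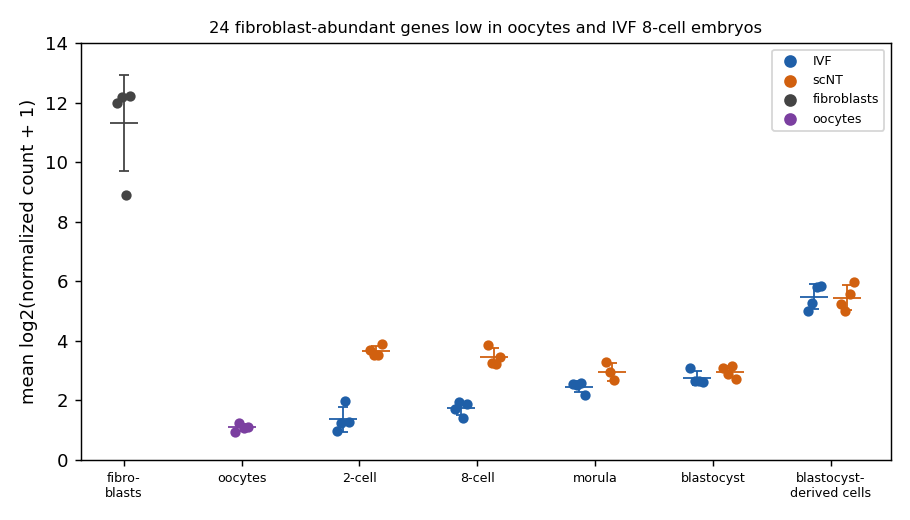
Mean log2(normalized count + 1) of the fibroblast-abundant genes chosen for the 2-cell stage, with 1 point per library and bars for the group mean ± SD. All scNT 2-cell libraries (at least 3.51) lie above all IVF 2-cell libraries (at most 1.97), while the IVF 8-cell libraries took part in the choice of these genes.

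At the 8-cell stage camera at the preset correlation called genes that rise in IVF development around this stage lower in scNT embryos, and the other set tests did not. The 1203 genes that rose at least 4-fold between the IVF 2-cell embryo and the IVF morula had a median log2 difference of -1.05 (camera adjusted p = 7.78e-50, and adjusted p = 0.199 with an estimated correlation). The 293 genes that fell over the same interval had a median of 0.64 (camera adjusted p = 4.36e-17, and adjusted p = 0.400 with an estimated correlation), which was 0.341 without IVF replicate 2. Library means of the sets gave exact permutation p = 0.0857 and 0.114 (n = 4 and 4). Within the same-numbered pairs the rising genes were lower in scNT embryos in 3 of 4 pairs and the falling genes higher in 4 of 4 (exact sign flips p = 0.25 and 0.125, where 0.125 is the smallest possible). By fry the adjusted p was 0.126 for rising, 0.156 for falling, 0.240 for oocyte-high and 0.544 for fibroblast-high genes. Oocyte-high genes had a median of 0.47 (camera adjusted p = 1.75e-14, and adjusted p = 0.602 with an estimated correlation), which was 0.269 without IVF replicate 2. Fibroblast-high genes had -0.57 (camera adjusted p = 9.95e-11, and adjusted p = 0.602 with an estimated correlation), which was 0.01 without scNT replicate 3, still below other genes by camera (adjusted p = 0.00393). It was -0.204 without IVF replicate 4 and -0.324, -0.866 and -1.044 without scNT replicates 1, 2 and 4. Of 13000 genes, limma called 0 at an adjusted p under 0.05, and 1642 had an unadjusted p under 0.05. DESeq2 called 378 genes, 21 higher and 357 lower, and edgeR called 0. With the replicate number as a block, which these libraries followed, limma called 168 genes, 13 higher and 155 lower, of which 96 lower and 0 higher were among the rising genes. Limma without the block called 82 genes without IVF replicate 4, 1 without scNT replicate 2, and 0 without any other single library.

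In morulae camera at the preset correlation and fry called oocyte-high genes, and genes that fall during IVF development, lower in scNT embryos. Camera with an estimated correlation did not. Of 13590 genes 2542 (18.7%) differed, 1002 higher with a median log2 difference of 0.70 and 1540 lower with a median of -1.20. A difference of at least 2-fold was seen for 190 higher and 996 lower genes (limma, Benjamini-Hochberg, n = 3 scNT and 4 IVF). The 901 oocyte-high genes had a median of -1.33, with 1 called higher and 442 called lower (camera adjusted p = 4.8e-38, and adjusted p = 0.212 with an estimated correlation; fry adjusted p = 0.0152). The number called lower was 240, 38, 165 and 171 without IVF replicates 1 to 4. The 403 fibroblast-high genes had a median of 0.37 (camera adjusted p = 1.14e-05, and adjusted p = 0.491 with an estimated correlation; fry adjusted p = 0.155), and 0.219 with equal library totals. Of the 2367 genes that fell at least 4-fold from the IVF 8-cell embryo to the IVF blastocyst, 2 were called higher and 1071 lower, with a median of -0.99 (camera adjusted p = 1.18e-55, and adjusted p = 0.114 with an estimated correlation; fry adjusted p = 0.0134). The number called lower was 626, 73, 400 and 414 without IVF replicates 1 to 4. The 1770 that rose had a median of 0.42 (camera adjusted p = 1.13e-11, and adjusted p = 0.223 with an estimated correlation; fry adjusted p = 0.0638), or 0.271 with equal library totals. Of the falling genes 662 were oocyte-high and 49 fibroblast-high, and the other 1656 had a median of -0.835 (camera adjusted p = 3e-37), with library means again apart. The library means of the oocyte-high, falling and rising sets did not overlap between methods (exact permutation p = 0.0286, the smallest possible; Benjamini-Hochberg adjusted 0.143, 0.114 and 0.114).

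The gene ENSBTAG00000046089 had 419.0 ± 87.3 normalized counts in scNT morulae (SD, n = 3) and 20.6 ± 12 in IVF morulae (n = 4; log2 difference 4.40 ± 0.37 SE, limma adjusted p = 0.00183). The gene ENSBTAG00000001585 had 37.3 ± 28.8 and 236.7 ± 65.3 (-3.18 ± 0.80 SE, adjusted p = 0.035). With equal library totals 404 genes were higher and 1924 lower, as the median of all genes moved from 0.05 to -0.11. Fewer genes were called in morulae without an IVF library: 1461, 114, 776 and 713 without replicates 1 to 4.

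**Figure D4:**
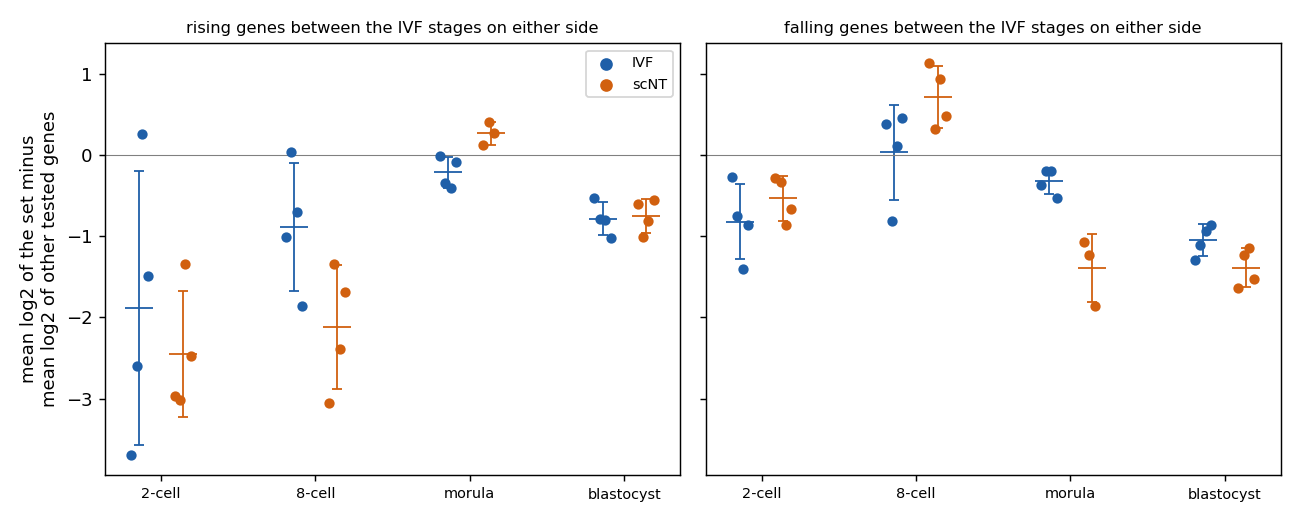
Mean log2(normalized count + 1) of the genes that rose or fell between the IVF stages on either side of each stage, minus the mean of the other tested genes, with 1 point per library and bars for the group mean ± SD. The scNT group means differed from the IVF means by 0.481 for rising and -1.066 for falling genes in morulae, and by -1.233 and 0.684 at the 8-cell stage.

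In blastocysts camera at the preset correlation and fry called oocyte-high genes lower in scNT than in IVF embryos, and camera with an estimated correlation did not. Of 12607 genes 750 differed, 319 higher with a median log2 difference of 0.79 and 431 lower with a median of -1.08, and 119 and 234 of these differed at least 2-fold (limma, Benjamini-Hochberg, n = 4 and 4). The 547 oocyte-high genes had a median of -0.35, with 12 called higher and 60 lower (camera adjusted p = 2.93e-07, and adjusted p = 0.212 with an estimated correlation; fry adjusted p = 0.0152). The numbers called higher and lower were 6 and 28 without IVF replicate 2, 7 and 25 without IVF replicate 3, and 3 and 24, 5 and 46, and 4 and 28 without scNT replicates 1, 3 and 4. Their share of all counts was 2.4 ± 0.99% in scNT and 2.14 ± 0.15% in IVF blastocysts (SD, n = 4 each; not tested). The higher scNT mean rested on replicate 3, at 3.79%, with replicates 1, 2 and 4 at 1.93%, 1.53% and 2.35%. The library means of the oocyte-high genes gave exact permutation p = 0.0286, the smallest possible. The median was -0.199 for genes at least 8-fold higher in oocytes. The 1646 falling genes had a median of -0.24 (camera adjusted p = 1.44e-07, and adjusted p = 0.253 with an estimated correlation; fry adjusted p = 0.0877), or -0.39 with equal library totals against -0.138 for other genes. The 1338 rising genes had a median of 0.05 and a mean of -0.02, and camera placed them above other genes with adjusted p = 0.360. That median was 0.12 without IVF replicate 1 and 0.11 without scNT replicate 2 (camera adjusted p = 0.0111 and 0.0179). With equal library totals it was -0.097 against -0.163 for other genes, so camera called the set higher than other genes (adjusted p = 0.0318). The 380 fibroblast-high genes had a median of -0.09 (camera adjusted p = 0.237), and 0.007 for genes at least 8-fold higher in fibroblasts (adjusted p = 0.834).

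The gene ENSBTAG00000039787 had 144.7 ± 18.7 normalized counts in scNT blastocysts and 0.325 ± 0.65 in IVF blastocysts (SD, n = 4 each; limma adjusted p = 7.41e-06). The gene ENSBTAG00000001998 had 2.80 ± 2.71 and 124.0 ± 28.6 (log2 difference -5.35 ± 0.53 SE, adjusted p = 0.000226). Equal library totals gave 175 higher and 928 lower genes, as the median of all genes moved from -0.01 to -0.16. The number called in blastocysts was 316 and 381 without IVF replicates 2 and 3, and 396, 451 and 378 without scNT replicates 1, 3 and 4.

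In blastocyst-derived cells 166 of 12390 genes differed, 79 higher in scNT cells with a median log2 difference of 1.11 and 87 lower with a median of -1.44 (limma, Benjamini-Hochberg, n = 4 and 4). The gene ENSBTAG00000000198 had 3133 ± 1770 normalized counts in scNT cells and 9.25 ± 5.98 in IVF cells, and ENSBTAG00000022971 had 921.8 ± 387 and 2.73 ± 1.45 (SD, n = 4 each; adjusted p = 5.47e-05 and 5.06e-06). The gene ENSBTAG00000010716 had 22.6 ± 23.4 and 311.9 ± 143 (adjusted p = 0.0186). Neither set differed by camera: the 472 fibroblast-high genes had a median of 0.04 (adjusted p = 0.336) and the 349 oocyte-high genes -0.03 (adjusted p = 0.267). Camera called the fibroblast-high genes without IVF replicate 3 or 4 (medians 0.14 and 0.14, adjusted p = 0.0141 and 0.0437) and the oocyte-high genes without scNT replicate 2 (-0.07, adjusted p = 0.0307). The number of genes called was 80, 80, 108 and 88 without IVF replicates 1 to 4, and 97, 93 and 89 without scNT replicates 1, 3 and 4. DESeq2 called 455 genes.

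The difference between the scNT step and the IVF step was tested for each interval. From the 2-cell to the 8-cell embryo limma called 0 of 13474 genes, with 644 at an unadjusted p under 0.05, while DESeq2 called 7 and edgeR 0. Limma called 94 without IVF 8-cell replicate 4 and 1 without scNT 8-cell replicate 3. From the 8-cell embryo to the morula the steps differed for 2644 of 14519 genes, 692 with a higher and 1952 with a lower change in scNT embryos. The gene ENSBTAG00000004891 had 44.0 ± 5.63 and 156.4 ± 6.52 normalized counts in scNT 8-cell embryos and morulae (n = 4 and 3). It had 45.9 ± 4.80 and 38.2 ± 7.69 in the IVF groups (SD, n = 4 each; limma, Benjamini-Hochberg adjusted p = 0.0083). The gene ENSBTAG00000004081 had 431.8 ± 45.2 and 48.9 ± 10.5 in the scNT groups and 308.0 ± 43.2 and 144.4 ± 29.3 in the IVF groups (adjusted p = 0.0083). The number called was 1615, 1746 and 4346 without IVF 8-cell replicates 2, 3 and 4, 1381 and 1708 without IVF morula replicates 2 and 3, 1342 and 1255 without scNT 8-cell replicates 1 and 3, and 1185 without scNT morula replicate 4.

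From the morula to the blastocyst the steps differed for 237 of 14439 genes, 142 with a higher and 95 with a lower change in scNT embryos. The gene ENSBTAG00000008596 had 983.0 ± 360 and 52.6 ± 10.6 normalized counts in IVF morulae and blastocysts and 187.4 ± 84.9 and 80.2 ± 4.43 in scNT embryos (SD, n = 3 for scNT morulae, 4 otherwise; limma, Benjamini-Hochberg adjusted p = 0.0122). Median-of-ratios scaling gave 283 higher and 59 lower. The number was 29 and 120 without IVF morula replicates 2 and 4, 64, 139 and 101 without IVF blastocyst replicates 2, 3 and 4, 42, 359, 81 and 41 without scNT blastocyst replicates 1 to 4, and 570 without scNT morula replicate 3.

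Between blastocysts and blastocyst-derived cells the steps differed for 208 of 13896 genes, 115 with a higher and 93 with a lower change in scNT cells. The gene ENSBTAG00000000198 had 4.15 ± 1.62 normalized counts in scNT blastocysts and 3133 ± 1770 in their derived cells. It had 18.5 ± 7.79 and 9.25 ± 5.98 in the IVF groups (SD, n = 4 each; limma, Benjamini-Hochberg adjusted p = 3.3e-08). Of the genes called with equal library totals, 282 were higher and 60 lower. The number was 110, 128 and 132 without IVF blastocyst replicates 2, 3 and 4, 96 and 125 without scNT blastocyst replicates 1 and 4, and 127 without scNT replicate 3 of the derived cells.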

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

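The tests of the explanations weighed in this part were all chosen after the pattern was seen, while the differences between the scNT and IVF steps were planned. Libraries far from the other 3 of their group were sought by the gap to the nearest library divided by the group's range. Of 94 groups of 4 values examined, 15 stood out. Chance gives about 1 in 20 for independent, normally distributed values. These included untransformed counts and several measures of the same libraries, so that rate need not hold here.

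Fibroblast replicate 3 stood apart in 4 measures. Its gap ratio was 0.935 for the fibroblast-high genes (mean log2 7.93, nearest 9.57) and 0.940 for the oocyte-high genes (2.39, nearest 1.37). It was 0.890 for the share of counts in the 10 highest genes (9.17%, nearest 15.0%) and 0.924 for the mean correlation with its group (0.846, nearest 0.934). Oocyte replicate 4 had a ratio of 0.849 for the share in the 10 highest genes (3.36%, nearest 3.15%). IVF 8-cell replicate 2 had 0.844 for the oocyte-high genes (7.29, nearest 7.96) and IVF blastocyst replicate 3 had 0.858 for the fibroblast-high genes (5.57, nearest 5.42). The scNT 2-cell replicate 3 had 0.851 for its correlation with its group (0.965, nearest 0.979). For total reads, IVF replicate 2 of the blastocyst-derived cells had 0.838 (9342097, nearest 8099262) and scNT 8-cell replicate 1 had 0.850 (15274177, nearest 9963462).

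Among named genes, ENSBTAG00000005250 had 4.60 normalized counts in IVF 2-cell replicate 3 and at most 0.60 in the other IVF 2-cell libraries (ratio 0.870). In IVF morulae, ENSBTAG00000046089 had 38.6 in replicate 1 against at most 16.3 (0.896) and ENSBTAG00000012363 had 48.1 in replicate 3 against at most 3.40 (0.959). In IVF blastocysts, ENSBTAG00000039787 had 1.30 in replicate 3 and 0 in the others (1.00). That value is 1 read in this library, and the ratio is 1.00 whenever all others are at 0.

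IVF 2-cell replicate 3 had 9.87% of its counts in its 10 highest genes, with the nearest library at 4.10% (ratio 0.856). In it 478 genes were at least 8-fold higher than the mean of the other IVF 2-cell libraries, 154 of them fibroblast-high. Of the 478, 72.4% were at least 8-fold higher in fibroblasts than in oocytes, and the median log2 of fibroblasts over this library was 0.57. With the 10 highest genes left out of the totals the fibroblast-high genes stood at 6.38, and at most at 4.14 in the others. This cannot decide whether a few genes taking many of the reads played a part. The step can only raise this library against the others, because its 10 highest genes held the largest share. An earlier activation of the embryonic genome stays open. Of the raised genes 57.7% were within 4-fold of this library or higher in IVF blastocysts. Neither this share nor the 72.4% was set against other genes, so neither can favour a cause. RNA of other cells cannot be told apart from an earlier activation. The median log2 of IVF blastocysts over this library was -1.23 with quartiles of -3.67 and 1.13. The scNT 2-cell replicate 3 lay apart in the same directions, by less. Its fibroblast-high genes stood at 4.47 and its oocyte-high genes at 8.28. The other scNT 2-cell libraries had at most 3.42 and at least 8.47. Deviations of the 2 libraries numbered 3 from their group means correlated at r = 0.627. Whether these 2 libraries share a cause was not tested.

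The scNT step differed from the IVF step by a test of the difference itself for 2644 genes from the 8-cell embryo to the morula, for 237 from the morula to the blastocyst and for 208 between blastocysts and derived cells. For the first of these, the lower oocyte-high genes of scNT morulae were weighed further. The authors' scaling is argued against, since the median log2 difference was -1.476 with equal library totals and -1.33 as deposited. A candidate explanation is that the scNT morulae were further along in development. The test left out the oocyte-high and fibroblast-high genes themselves. The remaining genes that rose between the IVF 8-cell embryo and blastocyst had a median of 0.429 and those that fell -0.835, and no scNT library overlapped an IVF library for either set. The like sets of other stages did not all go this way. At the 8-cell stage the directions were opposite, with medians of -1.051 for rising and 0.563 for falling genes. In blastocysts the medians were 0.070 (camera adjusted p = 0.185) and -0.194 (camera adjusted p = 3.9e-05). Libraries of the 2 methods overlapped for each of these sets. Only genes at least 32-fold apart were left out, while 2115 were at least 8-fold higher in oocytes, so other genes higher in oocytes may remain. The sets were also chosen after the principal components had placed scNT morulae between IVF morulae and blastocysts, so the test is not independent of that pattern. The origin of the embryos, which is the design's own difference, a different rate of loss of oocyte transcripts and the time of collection stay open as untested.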

How the results depend on the processing

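Of 1433 values of the 71 named results under an alternative, 1314 kept their call and direction, 119 lost the call and 0 reversed. Most of these genes had been picked for large changes or low p-values, so this says little about the other genes. The 21 gene lists were not run, because the files pair no identifier with a name. Alternatives that left out the 2-cell libraries numbered 3 or the 8-cell libraries numbered 4, the exact permutations of library means, the sign flips within pairs, the sets made without fibroblast replicate 3, all donor-gene lists and all tests of the rising and falling genes were chosen after seeing the data. The causes of the shifts were not tested. At a log2 change of 1, 28.8% of simulated changed genes were recovered at the 2-cell stage and 16.7% at the 8-cell stage.

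With the replicate number as a block, scNT against IVF called 168 genes at the 8-cell stage, where the libraries paired. Elsewhere same-numbered libraries were not paired by the rule (2-cell correlations 0.049 to 0.627, with 4 of 8 libraries closest to their own number), and the block gave 2 genes in morulae, 302 in blastocyst-derived cells, 44 for IVF 2-cell against oocytes, 114 for IVF 8-cell against 2-cell, 1440 for scNT 2-cell against oocytes, 323 for scNT 8-cell against 2-cell and 3776 for scNT blastocysts against morulae. In the other comparisons the block moved no count by over 1.5 times, giving 4 at the 2-cell stage and 821 in blastocysts, and it changed no call of a gene set.

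For scNT against IVF at the 2-cell stage (4 genes) library weights gave 8, edgeR 2, DESeq2 9 and leaving out both libraries numbered 3 gave 9. At the 8-cell stage (0) a pseudocount of 10 gave 3, no filter 2, equal totals 1, median-of-ratios scaling 1, all groups in a single fit 1084, library weights 11 and DESeq2 378. In morulae (2542) library weights gave 5223 and a 2-fold threshold 1186. In blastocysts (750) a single fit gave 312, library weights 1552 and a 2-fold threshold 353. In blastocyst-derived cells (166) library weights gave 444, a 2-fold threshold 105 and DESeq2 455. With each library left out in turn these numbers ranged from 0 to 8, 0 to 82, 114 to 2666, 316 to 860 and 80 to 134.

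For IVF 2-cell embryos against oocytes (130) no filter gave 75, a single fit 349, library weights 1172 and DESeq2 486. For IVF 8-cell against 2-cell embryos (34) pseudocounts of 10 and 0.5 gave 88 and 16, no filter 134, equal totals 22, median-of-ratios scaling 0, a single fit 2402, library weights 3782, edgeR 0 and DESeq2 667. For scNT 2-cell embryos against oocytes (2256) a single fit gave 435, library weights 3547 and a 2-fold threshold 429. For scNT 8-cell against 2-cell embryos (706) library weights gave 1997, a 2-fold threshold 239 and DESeq2 1517. A 2-fold threshold also lowered the later IVF steps to 3924, 4481 and 5406 genes and the scNT steps to the blastocyst and derived cells to 3777 and 5308. With each library left out the numbers ranged from 23 to 646 for IVF 2-cell embryos against oocytes, 0 to 1491 for IVF 8-cell against 2-cell, 789 to 2757 for scNT 2-cell against oocytes and 266 to 1059 for scNT 8-cell against 2-cell.

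For the difference between the steps from 2-cell to 8-cell (0) a single fit gave 2, library weights 1, DESeq2 7 and leaving out the 8-cell libraries numbered 4 gave 30. From 8-cell to morula (2644) leaving out those libraries gave 4716. From morula to blastocyst (237) a pseudocount of 10 gave 508, library weights 1428 and DESeq2 765. For derived cells against blastocysts (208) equal totals gave 342, a single fit 105, library weights 465 and DESeq2 412. With each library left out these ranged from 0 to 94, 1185 to 4346, 29 to 570 and 96 to 223.

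With an estimated correlation between genes no camera call of a set held. Calls were then lost with medians of -0.545 for the fibroblast-high and 0.254 for the oocyte-high genes at the 2-cell stage, -0.568 and 0.468 at the 8-cell stage, 0.369 and -1.334 in morulae and -0.352 for the oocyte-high genes in blastocysts. For rising and falling genes the medians were -0.545 and 0.326 at the 2-cell stage, -1.051 and 0.636 at the 8-cell stage, 0.423 and -0.987 in morulae and -0.242 for falling genes in blastocysts. By fry the calls held for the oocyte-high genes of morulae and blastocysts and the falling genes of morulae, and were lost for the others. After adjustment no exact permutation of library means passed, with differences of -0.320 and 0.276 (fibroblast-high and oocyte-high), -0.573 and 0.285 (rising and falling) at the 2-cell stage, -0.590, 0.504, -1.233 and 0.684 at the 8-cell stage, 0.443, -1.232, 0.481 and -1.066 in morulae, and -0.407 for the oocyte-high and -0.342 for the falling genes in blastocysts.

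With equal totals the fibroblast-high genes of 2-cell embryos had a median of -0.680 and lost the call, and the rising genes of blastocysts had -0.097 with other genes at -0.163, which gave a call above other genes. With sets at least 8-fold apart between fibroblasts and oocytes no call was gained or lost, and the uncalled fibroblast-high medians of blastocysts and derived cells were 0.007 and -0.003. Without their fibroblast-high and oocyte-high members the rising and falling sets gained or lost no call. With each library left out the fibroblast-high median ranged from -1.410 to 0.316 at the 2-cell stage, -1.044 to 0.010 at the 8-cell stage and -0.104 to 0.137 in derived cells. The oocyte-high median ranged from -0.007 to 0.383 at the 2-cell stage and -0.066 to -0.011 in derived cells (-0.070 for sets made without fibroblast replicate 3), with a call gained at -0.066 without scNT replicate 2, and the rising-gene median from -1.150 to 0.088 at the 2-cell stage and -0.035 to 0.118 in blastocysts. Equal totals moved the median of all genes from 0.071 to -0.064 at the 2-cell stage, and median-of-ratios scaling moved it from -0.167 to 0.033 for the scNT step from 8-cell to morula.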

Other observations

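The tests in this part were all chosen after the results were seen.

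Sequencing reads became concentrated in few genes as embryos developed. The 10 highest genes of a library took 3.19 ± 0.116% of the counts in oocytes (SD, n = 4). In IVF embryos they took 5.11 ± 3.20% at the 2-cell stage, 5.24 ± 1.02% at the 8-cell stage, 11.5 ± 1.83% in morulae and 22.1 ± 2.95% in blastocysts, and 14.02 ± 1.39% in blastocyst-derived cells (n = 4 each). In scNT embryos they took 3.66 ± 0.246%, 4.82 ± 0.221%, 13.6 ± 2.30% and 25.3 ± 4.21% and in the derived cells 12.5 ± 1.10% (n = 3 for morulae, 4 otherwise). The number of genes above 0 was 16863 ± 315 in oocytes, 17695 ± 211 in IVF and 17441 ± 595 in scNT 8-cell embryos, and 16874 ± 279 and 16893 ± 795 in the blastocysts.

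Genes that fibroblasts express strongly and that were low in oocytes and IVF 8-cell embryos were higher in scNT 2-cell embryos, by 2.30, or by 1.84 without the 4 called genes whose values led to the list. RNA of other cells, as may be present in IVF 2-cell replicate 3, stays open. That library stood at a mean log2 of 1.97 for these genes and the lowest scNT library at 3.51, but the choice removes genes that IVF 8-cell embryos express. For the 62 genes chosen by oocytes alone it stood at 5.36 and the lowest scNT library at 3.85, and 30 of the 62 were higher in scNT 2-cell embryos. Whether the transcripts were carried over with the donor cell also stays open. At the 8-cell stage all scNT libraries lay above all IVF libraries, by 1.75, or by 1.38 without those 4, but 23 of the 24 genes were those of the 2-cell list and were chosen for low values in IVF embryos. For genes chosen for low values in scNT embryos instead, the difference was 1.49 with no overlap at the 2-cell stage and 1.05 with overlap at the 8-cell stage (lowest scNT library 2.72, highest IVF library 2.76). Within the 8-cell pairs scNT was higher in 4 of 4 for each of these lists and for the genes chosen by oocytes alone (exact sign flips p = 0.125, the smallest possible). The fibroblast-high genes as a whole had medians below 0 at both stages (-0.545 and -0.568), which were 0.316 without IVF 2-cell replicate 3 and 0.010 without scNT 8-cell replicate 3. Across the 24 genes, which are not independent replicates, the level in scNT 2-cell embryos followed that in fibroblasts (Spearman's rho 0.76). The same value was not computed for IVF embryos, so it cannot favour a source of these transcripts. Transcription of these genes from the donor nucleus and transfer of molecules between libraries during preparation were not tested.

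Other divisions of the same libraries into groups of the same sizes were fitted to weigh chance. There were 35 divisions for each comparison of 2 groups and 100 drawn for each difference between steps. The smallest share is then 1 of 35 or 1 of 100, with no adjustment over comparisons, so chance cannot be excluded outright. In morulae (2542, highest other 2), blastocysts (750, highest other 3) and blastocyst-derived cells (166, highest other 74) only the real division of scNT and IVF (1) called as many genes. This argues against chance there, though the counts fell with some single libraries left out. The 74 came from replicates 1 and 2 of both methods against 3 and 4. At the 2-cell stage it is left open, since the real division called 4 genes and the highest other 3, and 0 were called without IVF replicate 2 or scNT replicate 1, 2 or 4. At the 8-cell stage the comparison says nothing about chance, because the real division called 0 genes, which any division reaches (highest other 81). There, with the replicate block, the real division called 168 genes and the other 7 that parted every pair called 0. With 8 such divisions the smallest share is 1 of 8, and the pairing was itself read from these libraries, so this cannot decide either.

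Within methods, chance is argued against where the highest other division called 0. These were the IVF steps from oocyte to 2-cell (130), 8-cell to morula (6148), morula to blastocyst (7996) and to derived cells (8762). They also included the same later steps of scNT embryos (9438, 6315 and 8571) and fibroblasts against oocytes (10335). Chance is also argued against for scNT 2-cell embryos against oocytes (2256, highest other 47). For scNT 8-cell against 2-cell embryos it is left open, since another division called 679 genes against the real 706, and the number ran from 266 to 1059 with single libraries left out. That division exchanged scNT 2-cell replicate 3 and scNT 8-cell replicate 3. Their fibroblast-high genes had mean log2 values of 4.47 and 3.34 and their oocyte-high genes 8.28 and 8.53. The 2-cell library thus lay further from oocytes than the 8-cell library, and the cause was not tested. Chance is not argued against for IVF 8-cell against 2-cell embryos (34), where 2 divisions called as many. The division that exchanged IVF 2-cell replicate 3 and IVF 8-cell replicate 4 called 1126, many times the real count, which points to a structure of these samples that their stage does not describe.

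For the differences between steps, the comparison says nothing about chance from 2-cell to 8-cell, where the real arrangement called 0 genes and the highest other 51. From 8-cell to morula (2644, highest other 284) and for derived cells against blastocysts (208, highest other 64) only the real arrangement called as many genes. Labels of method were exchanged within each stage. This therefore argues against chance only for methods that differ at neither stage. It cannot decide whether equal steps would give such counts by chance. From morula to blastocyst chance is left open, as 2 of 100 arrangements called at least the real 237. The other of these called 3401, many times the real count, which points to a structure of the samples. It kept the scNT morulae together and gave the scNT label to all IVF blastocysts, so it adds the differences between the methods at the 2 stages, and their shares were not tested.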
